A study of Homo sapiens with 4 samples.

How the data were processed

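The 4 libraries, 1 group labelled NoTx and numbered 1 to 4, came from cytoplasmic fractions of primary human RPE cells. Per the labels' protocols, cells were lysed in a mild detergent buffer for 15 min on ice, nuclei were pelleted at 1000 x g for 10 min, and single-stranded DNA of the supernatant was size-fractionated. It was made double-stranded and amplified for 20 to 25 cycles with a kit that enriches fragments of 200 to 800 bp, and sequencing libraries were then prepared. Nothing in the labels says whether the numbers stand for separate cultures or donors. No molecular identifiers are described, so copies of 1 molecule may be counted more than once, and Poisson intervals cover counting error only.

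The submitters' processing notes name STAR 2.5.3a, an aligner, featureCounts 1.6.1, a read counter, and the build hg19. The deposited table has the layout of featureCounts, per the file headers: gene symbol, chromosome, start, end, strand, length and 1 column of raw read counts. The count column names no library. Whether it pools the 4 libraries or holds a part of them, which reads were kept, whether only reads from Alu elements were counted, as the name of the table would allow, and the settings for strand and for reads with several placements are not given in the sources used here. The treatment of reads with several placements decides how many reads of a repeat family reach such a table. The table had 19802 rows, all named by gene. Length was End minus Start plus 1 in 100% of the rows with 1 interval, so whole gene spans were counted, introns included. Rows of the sex chromosomes are not reported here, which left 18905 autosomal rows (15 of them with several intervals) and 13 mitochondrial rows.

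Symbols were matched to a gene table of GRCh38.p14. Of the autosomal rows, 17565 (92.9%) matched, and 17564 of these overlapped the span given there, so the row coordinates are GRCh38. The published chromosome lengths of hg19, typed in by hand and not part of the deposited data, were used to find rows that start past the end of an hg19 chromosome. No annotation of hg19 was used, and coordinates were not converted between builds. In 32.9% of the rows (6223) the span overlaps another row. Reads were counted in more than 1 overlapping row, as seen in rows of 1 strand: 18 protocadherin gamma rows of chromosome 5 with starts from 141338760 to 141430589 and 1 shared end, 141512979, had counts from 65 down to 22, none above the count of the row starting before it. Totals over rows therefore count some reads more than once.

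From the counts, a rate was computed as reads per Mb of gene span. As there is 1 column, scaling counts by the column total changes each by 1 factor and was not done, and no count model such as edgeR's could be fitted. The test, group and replicate analyses planned for separate libraries and for Alu-named rows (Alu share, Alu families, Alu density, agreement between replicates) could not be made. Chromosome rates have 95% intervals from 2000 resamplings of 5-Mb regions within each chromosome. Intervals for single rows are exact Poisson intervals at 95%, and a count of 0 was taken to allow 3 reads. A gene list's rate was compared with 10000 random lists of the same size, matched on 10 classes of span length. The percentile describes this column and is not a p-value. The statistic fixed before the data were examined was the median rate over members; as most members of several lists held 0 reads, the rate of the whole list (summed reads over summed span) was added after seeing the data, as were the number of members with reads, matching on 50 length classes and leaving out the member with most reads. The planned lists with no row here (7SL and other small Pol III RNAs, ribosomal RNA, snoRNAs and microRNAs) had 0 members in this table and were not tested. The dispersion index is the mean squared difference between count and expectation over the expectation.

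Rows to name were fixed before the data were examined: the 10 rows with most reads, the 10 with the highest rate among rows of at least 500 bases and 10 reads, the first 2 members of each list by reads, and up to 5 for RPE identity. List members at 0 and DICER1 and EEF1A1 were named in addition, after their values were seen. The list comparison was tested on simulated data by the summed rate only, so the planned median was not tested. Simulated tables had 18905 rows with uneven counts. Of 20 tables each, 200 random rows changed by 0.5, 2 and 4 times fell outside the central 95% of matched lists in 19, 20 and 20. Unchanged rows did so in 1 of 20. Simulated rows were independent and the changed ones of any length, while real rows share reads and regions and some lists are of short rows. Shorter lists were less often found: of 20 tables each, a change by 0.5, 2 and 4 times was found in 14, 13 and 20 with 76 rows, in 6, 5 and 17 with 20 rows and in 3, 4 and 9 with 6 rows, so a short list inside the range of random lists is not shown to be unchanged. With simulated even reads the dispersion index was 1.01. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Alternatives covered low counts, overlapping rows, rows past the hg19 ends, length, the rows with most reads and the matching of random lists.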

Results

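The series profiled DNA recovered from the cytoplasm of primary human retinal pigment epithelial (RPE) cells, the pigmented layer that supports the photoreceptors. It asked about DNA copies of Alu elements, the abundant short primate repeats that are transcribed by RNA polymerase III and can be copied into DNA by reverse transcription. All 4 libraries carried the same label, NoTx, so the design held 1 group and no comparison between groups. The table analysed here held 1 count column that names no library: neither the spread between libraries nor the depth of each could be given, and no p-value was computed over genes. It listed protein-coding genes rather than Alu elements, so the share of reads from Alu elements and its split over the AluJ, AluS and AluY families were not analysed here. The name of the deposited table joins gene and Alu, and whether its counts are of all reads over a gene span or only of reads from Alu elements within it was not established, so each rate below can be read either way. The 18905 autosomal gene rows held 177275 reads over 1284 Mb of gene span, a rate of 138 reads per Mb. Intervals below cover counting error only, unless a resampling of regions is named.

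The row coordinates and the build named for the reads differed. The row coordinates were those of GRCh38: 17564 of 17565 rows matched by symbol overlapped the GRCh38 span of that gene. The submitters' processing notes name hg19 as the build. On chromosomes 5, 17, 18 and 20, 123 rows started past the end that the chromosome has in hg19. They held 0 reads over 3.36 Mb, against 574 expected at the rates of their chromosomes, and the 0 allows a rate of up to 0.893 reads per Mb. The 73 rows in the 2 Mb before those ends held 589 reads, 146 per Mb. ACTG1, which encodes cytoplasmic gamma-actin, was among the rows past the end of chromosome 17 and held 0 reads. Each value below is therefore the number of reads over the coordinates listed for a row, and was not established to be reads of the gene that names the row.

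**Figure D1:**
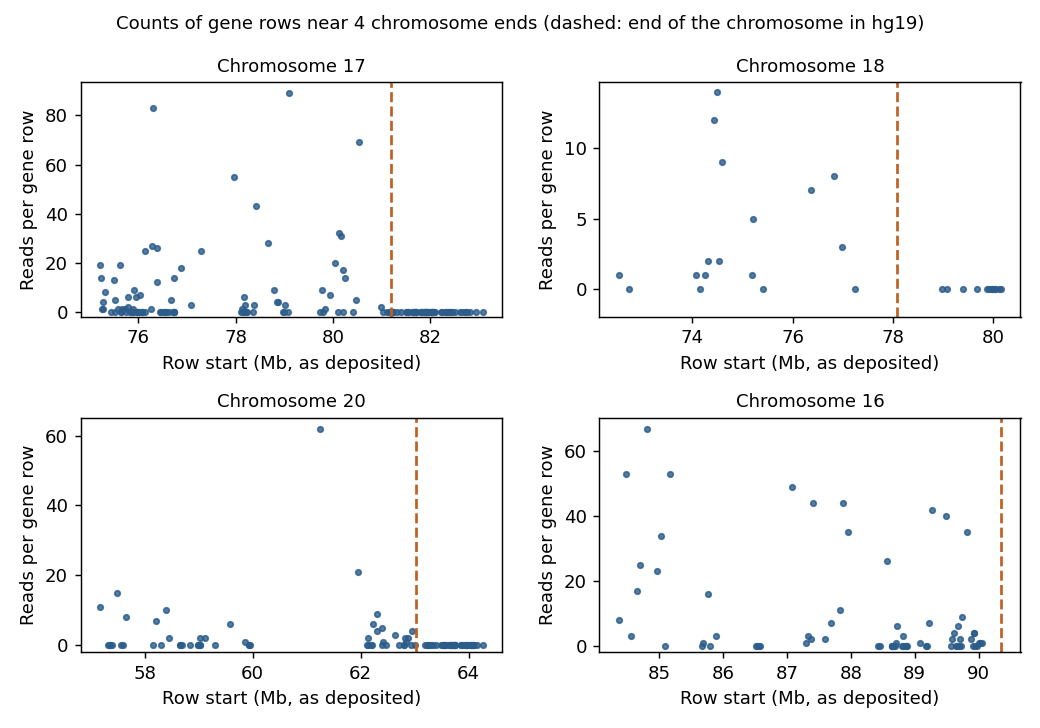
Reads per gene row (y axis) against the row's deposited start in Mb (x axis) near the ends of chromosomes 17, 18, 20 and 16; each point is 1 row and the dashed line is the end of the chromosome in hg19. Rows past the line on chromosomes 17, 18 and 20 all held 0 reads, and chromosome 16, whose rows all lie before the line, had 197 reads in its last 2 Mb.

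Reads were unevenly spread over the autosomes. Chromosome 19, which has many genes for its size, had the highest rate, 325 reads per Mb of gene span (95% interval from resampling 5-Mb regions, 277 to 367). Chromosome 16 followed with 227 reads per Mb (195 to 256), chromosome 17 with 217 (182 to 249) and chromosome 22 with 213 (177 to 243). The lowest rates were on chromosome 18, with 92.3 reads per Mb (67.6 to 113), chromosome 4, with 97.2 (80.4 to 120), and chromosome 13, with 97.8 (76.2 to 119). The interval of chromosome 19 overlapped that of none of the other autosomes, and its rate was 2.5 times the median of the others (2.16 to 2.92). Across the 22 autosomes the rate followed the number of gene rows per Mb of chromosome, which ran from 3.35 on chromosome 18 to 25.1 on chromosome 19. Pearson's r was 0.95 and Spearman's rho 0.90, each with a two-sided permutation p of 2e-05, the smallest that 100000 permutations can give. This relation was not among the planned analyses, and both p-values are unadjusted, also for the choice of the relation. Without chromosomes 17 and 19, the pair farthest from the median on that measure, r was 0.86. The chromosomes belong to 1 count column and are not replicates of the study.

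**Figure D2:**
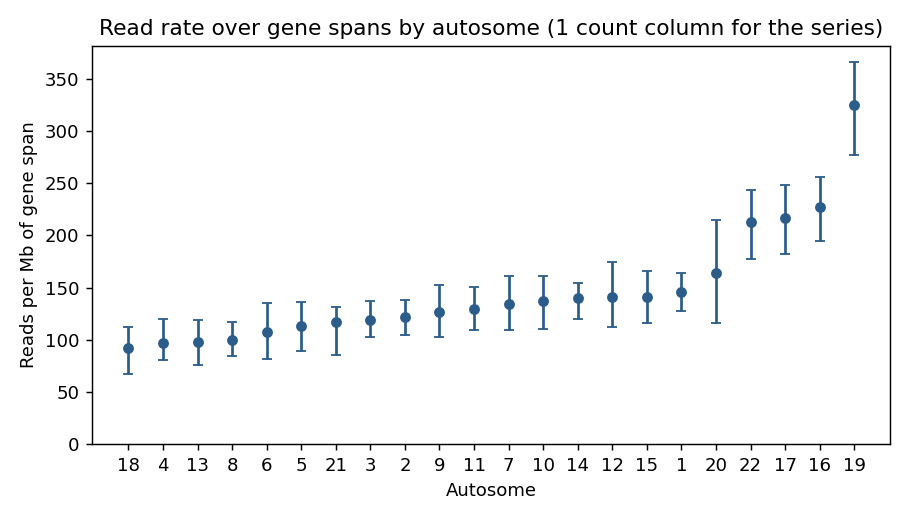
Reads per Mb of gene span (y axis) for each autosome, ordered by rate (x axis); points are the rate in the deposited column and bars are 95% intervals from resampling 5-Mb regions within the chromosome. Chromosome 19 lies at 325 reads per Mb, above the interval of every other autosome.

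Longer gene spans, introns included, held more reads. Over the 11090 rows with reads, Spearman's rho between count and length was 0.51 (0.50 to 0.53 from resampling 5-Mb regions), across genes, which are not independent replicates. The rate itself was lower in the longest rows: 109 reads per Mb in the class of 159 kb and more, against 217 in the class of 7.66 to 12.4 kb and 195 in the class of up to 3.75 kb. The 10 rows with most reads were all long, from 557 kb to 2.47 Mb, and together held 1.42% of the reads. NCKAP5 (chromosome 2, 132671799 to 133568463, GRCh38 coordinates as deposited) had 359 reads (exact Poisson 95% interval 323 to 398), HPSE2 (chromosome 10, 98457077 to 99235862) had 317 (283 to 354) and PTPRT (chromosome 20, 42072752 to 43189970), a receptor tyrosine phosphatase, had 305 (272 to 341). RBFOX1, a splicing regulator with the longest row in the table, had 279 reads but a rate of only 113 per Mb (99.9 to 127). LRMDA had 262 reads, WWOX 205, NRXN3, which encodes the synaptic protein neurexin 3, 204, CEP112 199, the transcription factor gene RUNX1 198 and SPOCK1 196. The NCKAP5 and HPSE2 rows had rates of 400 (360 to 444) and 407 (363 to 454) reads per Mb, both above the autosomal rate of 138.

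Among rows of at least 500 bases and 10 reads, the highest rates were in short rows, 9 of the first 10 under 10 kb. That follows in part from the limit of 10 reads, which a very short row passes only at a high rate. As a class, rows of up to 3.75 kb had 195 reads per Mb, and 91.2% of them held 0 reads. ELOA3C (chromosome 18, 46968695 to 46969912) held 20 reads in 1.22 kb, or 16420 per Mb (10030 to 25360). It overlaps another row and belongs to a family of near-identical copies, so its count is uncertain. PSORS1C2 held 24 reads in 1.82 kb, the taste receptor gene TAS2R5 15 reads in 1.15 kb, SPACA4 12 reads in 0.972 kb and the keratin-associated protein gene KRTAP5-9 12 reads in 1.14 kb. RESP18 (chromosome 2, 219327409 to 219333177) had more reads, 66 (51.0 to 84.0) in 5.77 kb, or 11440 per Mb (8848 to 14555). Copies of 1 molecule may be among them, so more reads are not shown to be more molecules. The intervals also do not cover the choice of these rows as the highest. DHDH on chromosome 19, which encodes dihydrodiol dehydrogenase, had 97 reads (78.7 to 118) in 11.3 kb, or 8593 per Mb. PSMB10, an immunoproteasome subunit, had 24 reads in 2.59 kb, KCTD11 28 in 3.06 kb and DPM2 27 in 3.39 kb. PSORS1C2, SPACA4 and PSMB10 also overlap other rows.

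Many rows held no reads. Of the autosomal rows, 7815 (41.3%) were at 0, where 2963 would be at 0 if reads fell evenly over the rows of each chromosome. The median row had 2 reads, and the 5045 rows with 10 or more held 87.1% of all reads. Among the 3403 rows of 100 kb or more, 162 were at 0, against 0.00386 expected under even coverage. The longest of these not past an hg19 end were C3orf67 (333 kb), PDE3A, a cyclic nucleotide phosphodiesterase gene (315 kb), PIP5K1B (304 kb), WDFY4 (298 kb) and EPDR1 (268 kb). An even spread over each chromosome would have given these 5 rows 39.5, 44.4, 38.6, 40.9 and 36.1 reads, in that order. The 5-Mb regions of PDE3A and WDFY4 had only 32.8 and 24.6 reads per Mb, and that of PIP5K1B fewer still. At the rates of their regions, far fewer reads would be expected in PDE3A, WDFY4 and PIP5K1B. The regions of C3orf67 and EPDR1 had 154 and 76.4 reads per Mb. All 5 rows were chosen after their values were seen. The 13 mitochondrial gene rows, from the mitochondrial genome rather than the nucleus, also held 0 reads over 11.4 kb. That allows up to 3 reads, or 0.00169% of the autosomal reads, while the autosomal rate alone would give 1.57 reads over that length.

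**Figure D3:**
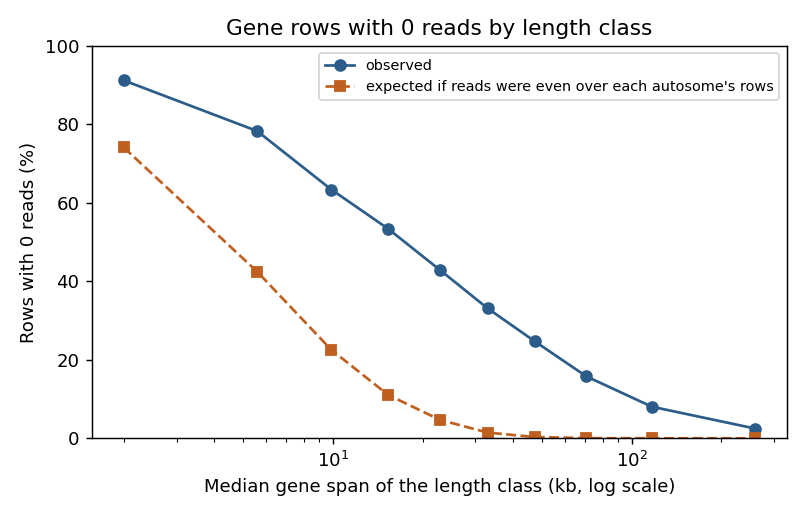
Share of autosomal gene rows with 0 reads (y axis, percent) in 10 classes of span length, plotted at the median length of the class in kb (x axis, log scale); circles are observed and squares are expected if reads were even over the rows of each autosome. The observed share falls from 91.2% to 2.49% and stays above the expected share in each class.

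By the summed rate, added after seeing the data, rows named for genes that mark RPE cells lay near the low edge of matched lists. They were inside or outside it depending on the setting, and well inside by the other measures. As 13 lists were ranked, each under several settings, 1 list near an edge would not be unusual. The summed rate also weighs long rows most: MITF, with 4 reads, spans 229 kb of the list's 1.01 Mb. Of the 18 RPE identity rows, 9 held reads, 60 in all, a rate of 59.4 reads per Mb for the list. The central 95% of random lists of the same size and span lengths had rates from 59.1 to 258, and the list lay at percentile 2.58 of 10000 such lists. LRAT, which esterifies retinol in the visual cycle, had 18 reads, and TRPM1, a cation channel gene of melanocytes and retina, had 16. SERPINF1, which encodes the secreted factor PEDF, had 11, and the pigment cell genes MITF and TYR had 4 each. By rate the order differed: SERPINF1 had 704 reads per Mb (352 to 1260), LRAT 143, TRPM1 99.9, TYR 33.8 and MITF 17.5. RPE65, the retinoid isomerase of the visual cycle, BEST1, PMEL, OTX2 and KRT8 were at 0. By the statistic fixed beforehand, the median rate over members, the list was at 8.74 reads per Mb and percentile 15.8. The central 95% of random lists ran from 0 to 162, so no list could lie below it. In planned settings the median was at percentile 12.7 over rows that held reads. It was at 21.2 for counts not divided by length, against unmatched lists. The number of rows with reads, added after seeing the data, was at percentile 17.8 (central 95% of random lists, 7 to 14). By the summed rate, the list was at percentile 3.44 when the member with most reads, here LRAT, was left out of it and of each random list, at 1.61 with random lists matched on 50 length classes in place of 10 (central 95% 66.2 to 281), and at 7.32 with only rows that overlap no other row.

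Rows named for genes with abundant cytoplasmic mRNA lay within the central 95% of matched lists. Their median span was 9.37 kb, and their counts were not established as reads of those genes. The list had reads in 8 of 20 rows and a rate of 126 reads per Mb, at percentile 25.4 of matched lists. ACTB, which encodes beta-actin, had 19 reads, YWHAZ 7 and the translation factor gene EEF1A1 2, while GAPDH was at 0. Without ACTB the list had 78.9 reads per Mb, at percentile 24.7 of random lists that also left out their member with most reads. Of 76 rows of cytosolic ribosomal proteins, 24 had reads, a rate of 189 per Mb at percentile 56.3. RPS9, whose row overlaps another, had 25 reads (518 per Mb) and RPL13A 17 (3575 per Mb). The central 95% of random lists matched to the ribosomal proteins had 93.0 to 314 reads per Mb, and a rate between these would not have been detectable as different.

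Rows named for olfactory receptors, a family clustered in the genome and silent in most tissues, had the lowest summed rate relative to matched lists of the lists tested. Counts of such short rows were not established as reads of those receptor genes. Reads were found in 34 of 357 rows, 164 in all, a rate of 76.0 reads per Mb. The central 95% of random lists matched on 50 length classes had reads in 52 to 76 rows. None of the 10000 length-matched random lists was as low, and the central 95% of them had rates from 130 to 260. The random lists drew rows singly over the autosomes, not in clusters. As rates differ by region, their range may be too narrow for a clustered family, and the percentile is not shown to be a trait of these genes. OR7C1 had 30 reads and OR2AT4 25. The median rate over members, the statistic fixed beforehand, was 0 both in this list and in its random lists and could not show a difference. With only rows that held reads, a planned setting, the median was 304 reads per Mb at percentile 37.9, inside the range of random lists. The histone list had reads in 5 of 70 rows, led by HIST1H2BC and HIST1H2BD with 5 each, and a rate of 101 per Mb at percentile 15.0, or 172 per Mb at percentile 49.7 with only rows that overlap no other row.

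Rows named for markers of other cell types lay within the central 95% of matched lists, by the summed rate used here for each list. Fibroblast genes had 101 reads per Mb (percentile 24.0), with 12 reads for the collagen gene COL1A2 and 11 for LUM. Endothelial genes had 77.5 per Mb (percentile 19.8), with 30 reads for FLT1, a VEGF receptor, and 8 for PECAM1. Leukocyte genes had 178 per Mb (percentile 63.1), with 24 reads for PTPRC and 18 for CSF1R. Photoreceptor genes had 122 per Mb (percentile 37.6), with 13 reads for PDE6B and 6 for CRX, and melanocyte genes 78.8 per Mb (percentile 19.4), with 8 reads for MLANA and 5 for SOX10. TYR, DCT and PMEL are in both the melanocyte and the RPE identity list, so those lists are not independent. Genes of Alu RNA processing and cytosolic nucleic acid sensing had 146 reads per Mb (percentile 42.8). DROSHA, the nuclear microRNA-processing nuclease, held 51 of their 82 reads, SAMHD1 held 9 and DICER1, whose product cleaves Alu RNA, held 6. The 11 long genes of common fragile sites all had reads, 1612 in total, at 81.2 per Mb (percentile 16.9), with RBFOX1 and WWOX first. Their median span was 1900 kb, far above that of the longest of the 10 length classes, 259 kb. Matched on 50 length classes, the list was at percentile 41.2 (central 95% 54.7 to 133). Reads in all 11 rows follow from length, as the central 95% of those random lists was 11 to 11. Single rows carried several of these rates, here ranked against random lists that also left out their member with most reads: without DROSHA its list had 71.8 reads per Mb (percentile 21.5), without FLT1 the endothelial list 46.2 (percentile 13.9), without PDE6B the photoreceptor list 59.1 (percentile 43.2) and without MLANA the melanocyte list 49.7 (percentile 29.4). With only rows that overlap no other row, the melanocyte list had 32.4 reads per Mb (percentile 10.3). That setting leaves out 3 of its 6 rows, MLANA and SOX10 among them, so few rows remain. The nuclear copies of mitochondrial 16S rRNA had 1 read in 10 rows, in MTRNR2L4, and 0 in the other 9, MTRNR2L1 among them.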

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

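The planned fits on TMM-scaled values, with DESeq2 size factors and leaving out each library were not run, because the table has 1 count column. No paired analysis was possible because there is 1 group and the count column carries no replicate number. The rise of counts with span length (Spearman's rho 0.51) stayed positive: 0.45 with only rows of at least 10 reads, as planned, and 0.66 with rows at 0 included, chosen after seeing the data. The rate of chromosome 19 over the median of the other autosomes (2.5) was 3.09 with only rows of at least 10 reads and between 2.40 and 2.51 under the other 4 settings. For 11 of the 13 lists the central 95% of random lists by the median rate started at 0, and for 4 of these (ribosomal proteins, nuclear 16S copies, histones and olfactory receptors) it was 0 throughout, so the planned statistic could not place them below it and settings on the same side show no stability. For RPE identity, the planned settings put the list inside the range, at percentile 12.7 with only rows that held reads and 21.2 with counts not divided by length. The number of rows with reads (50 length classes), chosen after seeing the data, was at percentile 18.9. In settings also chosen after seeing the data, matching on 50 length classes moved the summed rate from percentile 2.58 to 1.61, and using only rows that overlap no other row moved it to 7.32. Leaving out LRAT, the member with most reads, gave 1.21, a fall by construction, as the random lists kept theirs; with it left out of these too the list was at 3.44. For the long genes of fragile sites, counts not divided by length put the list at percentile 100 of unmatched lists, by construction, since longer rows hold more reads. For the same reason the short olfactory receptor rows were at percentile 0.04 in that setting, which shows nothing more than their length. With only rows that held reads they were at percentile 37.9. Under settings chosen after seeing the data, the number of rows with reads (50 length classes) and the summed rate were at percentile 0, the rate also with 50 length classes, without OR7C1 (whether or not the random lists also left out their first member), without rows past the hg19 ends and with lists matched on chromosome; with only rows that overlap no other row it was at 0.04. In none of these settings were random rows drawn in clusters, as olfactory receptor rows lie. In the shortest of the 10 length classes 91.2% of rows held 0 reads, where 74.1% would at this depth with even reads.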

Other observations

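In 5-Mb regions with at least 10 rows (495 regions, those past an hg19 end left out), the median rate was 120 reads per Mb of gene span. Chromosome 19 supplied 5 of the 10 regions with the highest rates, among them 45 to 50 Mb with 416 reads per Mb (396 to 437), 15 to 20 Mb with 414 and 5 to 10 Mb with 407. The first 5 Mb of chromosome 17 had 337 reads per Mb, 120 to 125 Mb of chromosome 12 also 337, and 30 to 35 Mb of chromosome 6, where the major histocompatibility complex lies, 308 (288 to 328). Low rates were found at 70 to 75 Mb of chromosome 6, with 26.7 reads per Mb (20.6 to 33.9), and at 45 to 50 Mb of chromosome 14, with 18.2 (11.8 to 26.9). The 15 rows between 5 and 10 Mb of chromosome 21 held 0 reads, against 27.0 expected at the rate of that chromosome, and the 11 rows between 15 and 20 Mb of chromosome 14 held 1 read, against 29.5. Only rows past an hg19 end had been left out. Whether hg19 has sequence at these coordinates that could take reads was not examined, so these expectations may not apply.

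Of the explanations weighed next, that of the genome builds was tested only after its result had been seen. The rows after CHMP6 on chromosome 17, after MBP on chromosome 18 and after SLC17A9 on chromosome 20 were all at 0, runs of 65, 13 and 42 rows where 362, 88.3 and 156 reads were expected. Few reads near chromosome ends in general are argued against: the last 2 Mb of the other 18 autosomes held reads in 17 of them, at 0.71 times the autosomal rate. Reads placed on hg19 and counted over GRCh38 spans would leave 0 reads past the hg19 ends, and 0 reads were found in those 123 rows. The run at the end of chromosome 5 (13 rows, 22.6 reads expected) holds more rows but fewer expected reads than one on chromosome 10 (9 rows, 29.3 expected) and would show nothing alone. If that hypothesis holds, counts of short and long rows alike may belong to other genes than the named ones. The offset differs along each chromosome and was not measured here, so no row length is shown to be free of it. How far rates of chromosomes and regions would move was not tested.

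Shorter genes on chromosome 19, reads counted in several overlapping rows and a few rows with very many reads are each argued against as the cause of its higher rate. Its ratio to the median of the other autosomes was 2.40 (1.91 to 2.83) after standardising to the length classes of all rows, 2.43 (2.06 to 2.91) over rows that overlap no other row and 2.51 (2.20 to 2.95) without the 10 rows with most reads of each chromosome. GC content and amplification bias, and a higher number of Alu elements on gene-rich chromosomes, above all if only reads from Alu elements were counted, remain open and were not tested, as neither sequence nor repeat annotation was used here. The design names no second group, so no biological explanation was tested.

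Counts varied between rows far more than even coverage gives. The dispersion index was 17.6 with the rate of each chromosome as the expectation. It was still 13.3 with the rate of each 5-Mb region as the expectation, and 16.7 over rows that overlap no other row, so regional differences of that size and shared reads are argued against as the whole cause. Copies of 1 molecule made by amplification cannot be told apart from many molecules of 1 source, since positions of single reads were not used here. Counting only reads from Alu elements could also leave rows without such elements at 0, the mitochondrial rows and many olfactory receptor rows perhaps among them; this remains open and was not tested. Of the rows with reads, 14.1% held exactly 1.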
